A study of Mus musculus with 9 samples.

How the data were processed

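Single-nucleus chromatin accessibility (snATAC-seq) was measured in the pancreas of 9 wild-type mice of 6 to 7 weeks, in 3 groups of 3: controls given saline and sacrificed at day 28, mice sacrificed at day 7 after cerulein and mice sacrificed at day 28 after cerulein. Per the labels' protocols, cerulein was injected 8 times at hourly intervals on each of 2 consecutive days. The treatment label gives the dose as 50 mg per kg and the protocol as 50 µg per kg. Per the labels' protocols, flash-frozen pancreas was pulverised, nuclei were isolated in citric acid and sucrose, 10000 nuclei were loaded per library with the ATAC part of a 10x Multiome kit, and libraries were sequenced on a NovaSeq. Littermates were used, and each group had its own cage. Libraries were pooled from 6 sequencing runs, except day 7 replicate 2 and day 28 replicate 3 with 4.

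The deposited files hold raw counts per peak and nucleus, and all 9 use the same 62138 peaks (median width 857 bp, GRCm38). Per the submitters' processing notes, Seurat and Signac were used with the mm10 genome; their versions, the aligner and the peak caller are not given in the sources used here. Of the non-zero values 45.9 to 53.8% per library were 2 and 17.0 to 21.1% were 1, and whether both fragment ends were counted is not given in the sources used here. No normalised table was analysed here. No doublet caller was run, and leaving out the 5% deepest nuclei of each library was the alternative for doublets. Barcodes shared between libraries were near the number expected by chance for most pairs, and furthest from it at 24 against 12.2 for day 7 replicate 3 with day 28 replicate 3 and at 7 against 14.1 for day 7 replicate 1 with day 28 replicate 3.

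Depth ranged from 39.7 M counts (day 28 replicate 3) to 90.7 M (day 7 replicate 1), and each test compared 3 libraries with 3. With changes put into 200 genes or peaks of simulated data, edgeR called at day 7 in acinar-like nuclei 77% of 1.5-fold and 97% of 2-fold changes for genes, with 14 false calls, and 25% and 78% for peaks, with 13 false calls. Over all nuclei it called 73% and 98% for genes (7 false calls) and 26% and 84% for peaks (8 false calls). In other classes it called 30% and 63% (ductal-like, 3 false calls), 13.3% and 51.5% (fibroblast-like, 2), 1.1% and 30.9% (macrophage-like, 0) and 1% and 8.4% (endothelial-like, 1). DESeq2 called 82% and 96% for genes in acinar-like nuclei, with 37 false calls. In simulated day 28 data without change edgeR gave 0 calls for genes over all nuclei and in each class except fibroblast-like nuclei (1), 0 for acinar-like peaks and 3 for all peaks, and DESeq2 gave 4 for acinar-like genes. Each gene or peak was drawn independently of the others in these simulations. They therefore hold no difference shared by many genes of a library, and the rates may be too favourable for the real libraries.

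Peaks were assigned to genes where they lay in the gene body or within 2 kb of it on both sides. The plan named 2 kb upstream, but the gene table gives no strand, so both sides were used, and a promoter-only alternative was replaced by peaks within 2 kb of either gene end. Of 21887 genes 15592 had a peak, 42793 peaks (68.9%) lay in a gene region and 6.2% in at least 2, so neighbouring genes share counts. Of all peaks 28.6% lay at gene ends. Motif accessibility, its alternatives with other backgrounds and the promoter-only alternative were planned and not run, because no genome sequence and no strand were at hand.

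Nuclei were clustered on term frequency and inverse document frequency values followed by a singular value decomposition with 20 components (latent semantic indexing) in double precision, rounded to 4 decimals. Component 1 was left out, as its correlation with log10 depth was 0.984, above the limit of 0.75, and 19 were used. A graph of 30 nearest neighbours with Jaccard weights was partitioned with the Leiden method at a resolution of 0.5 (alternatives 0.25 and 1.0). A first run used single precision, in which the partition could not be repeated exactly. The change to double precision was made for that reason alone, after results of the first run had been seen, and everything reported is from the second. An alternative changing every coordinate at random by at most 0.001 was added after the data were seen. Sub-clusters within acinar-like nuclei were unstable at this level (adjusted Rand index 0.77), and acinar-like nuclei themselves were not (24239 of 24244 in both). Clusters were named where the median log2 fold of a class's markers over other nuclei was above 1 and at least 3 markers were over 2-fold, with genes of at least 10 CPM ranked. Unnamed clusters were then compared with the pooled named ones, which is how acinar-like clusters were named.

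Counts were summed per library, over all nuclei and per class, and tested by edgeR's quasi-likelihood F test with all 9 libraries in 1 model, TMM scaling, filterByExpr and Benjamini-Hochberg adjustment, with a threshold of adjusted p 0.05. Without any change a share of about 0.05 of the tested genes or peaks would have an unadjusted p under 0.05. Classes other than acinar-like were tested where every library had at least 30 nuclei. Endocrine-like nuclei, with as few as 19, were not. Shares were tested exactly over 280 splits of 9 libraries into 3 groups on the arcsine square root scale. Gene lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, and with fry. There were 15 gene lists (acinar digestive enzymes, acinar transcription factors, acinar-to-ductal metaplasia and injury, Reg family, AP-1 and immediate early, unfolded protein response, NF-kB and cytokines, interferon response, extracellular matrix, proliferation, MAPK feedback, YAP and TEAD targets, Notch, Wnt and Hedgehog, and cytosolic ribosomal proteins and housekeeping as controls). There were 16 marker lists, of which neutrophil, with 2 measured genes, was not tested. Log2 CPM used a prior count of 2. CPM in the text is edgeR's, scaled by the library sum and its TMM factor.

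The lists, tests, comparisons, processing choices to vary and naming rule were fixed before the data were examined. By the naming rule a comparison's 10 largest rises and falls of genes, and 5 of peaks, were named among those with adjusted p under 0.05, mean log2 CPM above the median of those tested and libraries fully separate; names of the forms Gm and Rik were left out, and members of the fixed lists could be named. Results of some list members are not reported here. For other classes the 5 largest were named.

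Alternatives were relative log expression scaling, no filter, DESeq2, replicate number as a block, each library left out in turn, both 4-run libraries left out, no 5% deepest nuclei, thinning of every library to the smallest total (39.7 M counts over all nuclei, 36.5 M in acinar-like nuclei), binarised counts and the cluster resolutions. Those added after the data were seen were the largest acinar-like cluster, nuclei of 5000 to below 30000 counts, leaving out control replicate 2 and day 28 replicate 2, the share of counts at gene ends as a covariate, gene ends only and the random change of coordinates. Replicate numbers were not treated as pairs, since only 4 of 9 libraries correlated best with their own number and same-number correlations ran from -0.31 to 0.49. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.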

Results

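Chromatin accessibility was measured nucleus by nucleus in the pancreas of 9 wild-type mice, to ask how it differed 7 and 28 days after an acute pancreatitis. Pancreatitis was induced with cerulein, a peptide analogue of cholecystokinin that overstimulates the acinar cells, which make the digestive enzymes. Each cerulein mouse received 8 hourly injections on each of 2 days. Of the cerulein mice, 3 were sacrificed at day 7 and 3 at day 28, and 3 mice given saline, the controls, at day 28. The day 7 mice therefore differed from the controls in time since injection as well as in treatment. Each group had its own cage, so cage and group cannot be told apart. The cerulein dose is 50 mg per kg in the treatment label and 50 µg per kg in the protocol, and the doubt was not settled here.

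The 9 libraries held 32329 nuclei and 564.8 M (mega) counts over 1 common set of peaks. The control libraries totalled 40.8, 70.8 and 69.6 M counts, the day 7 libraries 90.7, 68.8 and 74.7 M, and the day 28 libraries 56.3, 53.5 and 39.7 M, in replicate order. Nuclei numbered 3688 ± 889 per control library, 4547 ± 1353 per day 7 library and 2541 ± 667 per day 28 library (mean ± SD, n = 3 each). The median nucleus of a library had between 8573 counts (day 7 replicate 1) and 12151 counts (day 28 replicate 3). Day 7 replicate 2 and day 28 replicate 3 were pooled from 4 sequencing runs and the other libraries from 6, so no group consisted of 4-run libraries alone.

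Clustering by accessibility gave 10 clusters. Acinar-like nuclei, with accessible digestive enzyme and Ptf1a regions, numbered 24244 in 5 clusters. Smaller clusters were ductal-like (3671 nuclei), fibroblast-like (1789), endothelial-like (1018), macrophage-like (979) and endocrine-like (628). The fibroblast-like cluster also carried the mesothelial markers, and the macrophage-like cluster was led by leukocyte genes such as Cyth4, Itga4 and Cd74. Ductal-like nuclei were shallow, at 0.35 of the median depth of their own library. Their leading genes were Slc2a2, Evc, Wnt7b, Gabrp and Hhex, none of them a marker fixed for duct, and at the higher cluster resolution 3248 of such nuclei stayed unnamed. Endothelial-like nuclei stood at 0.28 of their library's median depth, with Tie1 and Kdr among their leading genes.

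No class of nuclei differed detectably in share between the groups. Acinar-like nuclei were 75.67 ± 5.66% of nuclei in controls, 75.46 ± 9.35% at day 7 and 75.49 ± 1.77% at day 28 (mean ± SD, n = 3 mice each). Ductal-like nuclei were 9.96 ± 2.06%, 12.05 ± 5.27% and 10.33 ± 2.68%, fibroblast-like nuclei 5.55 ± 1.64%, 5.16 ± 1.50% and 6.15 ± 1.04%, and macrophage-like nuclei 3.69 ± 1.72%, 2.76 ± 0.73% and 2.79 ± 0.62%, in the same order. Endothelial-like nuclei were 3.56 ± 0.70%, 2.53 ± 1.20% and 3.37 ± 0.67%, and endocrine-like nuclei 1.57 ± 0.26%, 2.04 ± 1.68% and 1.88 ± 0.52%. An exact permutation test over the 280 splits of the 9 libraries into 3 groups gave adjusted p = 0.996 for every class. Unadjusted, the lowest of these exact p was 0.436, for endothelial-like nuclei. With edgeR on the counts of nuclei the lowest adjusted p was 0.936. Comparing 2 groups of 3 by exact permutation cannot give a p below 0.1.

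**Figure D1:**
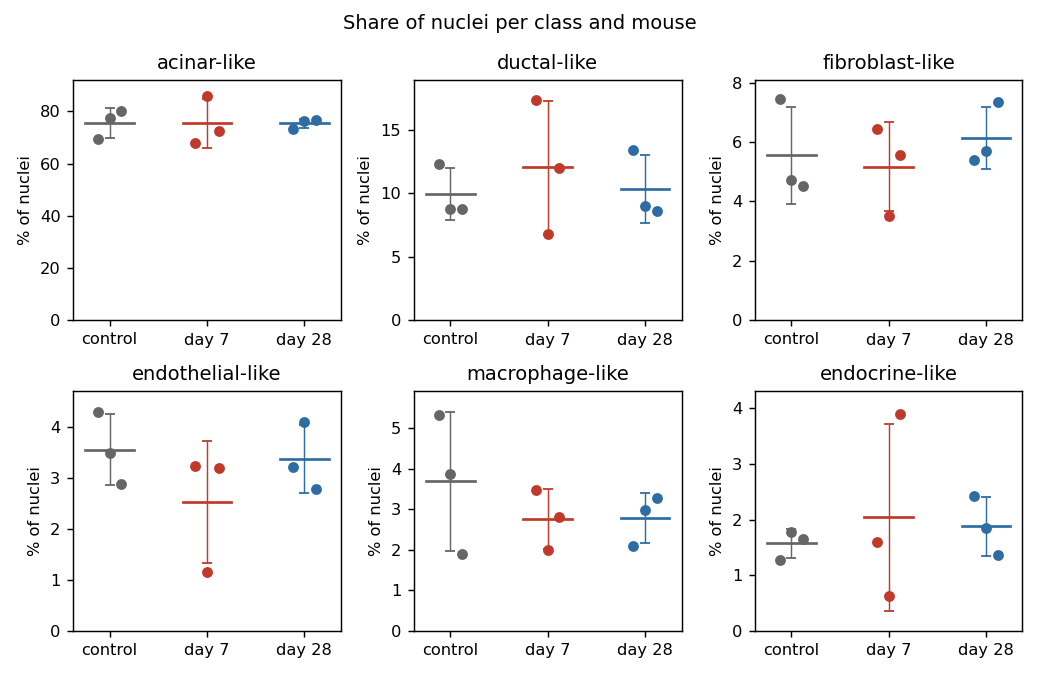
Share of nuclei (% of all nuclei of the library) per class; each point is 1 mouse, the bar is the group mean and the whiskers are the SD (n = 3 per group). Acinar-like shares averaged 75.67% in controls, 75.46% at day 7 and 75.49% at day 28.

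At day 7 the acinar-like nuclei were more accessible than in controls at 16 gene regions and less accessible at 0. Among those named by the rule, Nab2, a corepressor of EGR transcription factors, rose from 62.45 ± 7.44 to 107.2 ± 15.8 CPM (counts scaled to a common library total; mean ± SD, n = 3 mice each; log2 change 0.78 ± 0.11 SE, edgeR adjusted p = 0.0294). Anxa2, a calcium-dependent phospholipid-binding protein, rose from 60.39 ± 8.65 to 96.61 ± 7.48 CPM (0.68 ± 0.11, adjusted p = 0.0423). Ets1, a transcription factor, rose from 45.42 ± 4.66 to 71.9 ± 8.59 CPM (0.66 ± 0.11, adjusted p = 0.0427). Gsn, which encodes the actin-severing protein gelsolin, rose from 80.17 ± 5.1 to 111.0 ± 3.65 CPM (0.47 ± 0.08, adjusted p = 0.0423). These genes lie on chromosome 10 at 127660918-127666703, chromosome 9 at 69453683-69491792, chromosome 9 at 32636241-32757820 and chromosome 2 at 35256359-35307902 (GRCm38). At each of the 16 regions every day 7 mouse stood above every control mouse.

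The rise with the largest log2 change, singled out after its values were seen, was at Ajap1, a membrane protein associated with adherens junctions (chromosome 4, 153373221-153483795). Ajap1 rose 4.61-fold, from 12.36 ± 4.52 to 56.67 ± 12.3 CPM (log2 change 2.21 ± 0.30 SE, edgeR adjusted p = 0.0294, n = 3 each). The other genes that rose, likewise outside the naming rule, were Atp1b1 (1.27), a subunit of the sodium pump, B3gnt3 (1.26), a glycosyltransferase, Cblif (1.14), which encodes the cobalamin carrier intrinsic factor, and Fam3b (1.00), a secreted cytokine-like protein. With them rose Pxdc1 (0.94), Dsg4 (0.92), a desmosomal cadherin, Dhrs9 (0.87), 1700017B05Rik (0.87), Phldb2 (0.76), Elf4 (0.52), a transcription factor of the ETS family, and Synpo (0.48), an actin-associated protein. Cluster 1 was the largest acinar-like cluster in every group, but clusters 2, 3 and 5 were unevenly spread over the groups, and in day 7 replicate 2 cluster 2, led by Ajap1 and Cblif, was the largest, and in control replicate 2 and day 28 replicate 2 cluster 3, led by Cdh12 and Cngb3. Cluster sizes were not compared between groups, because the clusters were built with these genes.

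These calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15592 genes, in which 13.2% of genes had the 3 day 7 and the 3 control mice fully apart, against 10% by chance. The count of 16 became 0 without control replicate 3, without day 7 replicate 2, without both 4-run libraries, with the share of counts at gene ends as a covariate, or among nuclei of 5000 to below 30000 counts. It was 2 without control replicate 1, 6 without control replicate 2, 2 without day 7 replicate 1, 4 without day 7 replicate 3, 10 without day 28 replicate 2, 6 without day 28 replicate 3, 8 without the 5% deepest nuclei, 8 in the largest acinar-like cluster, 6 at gene ends only, 8 without control replicate 2 and day 28 replicate 2, and 123 with DESeq2.

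**Figure D2:**
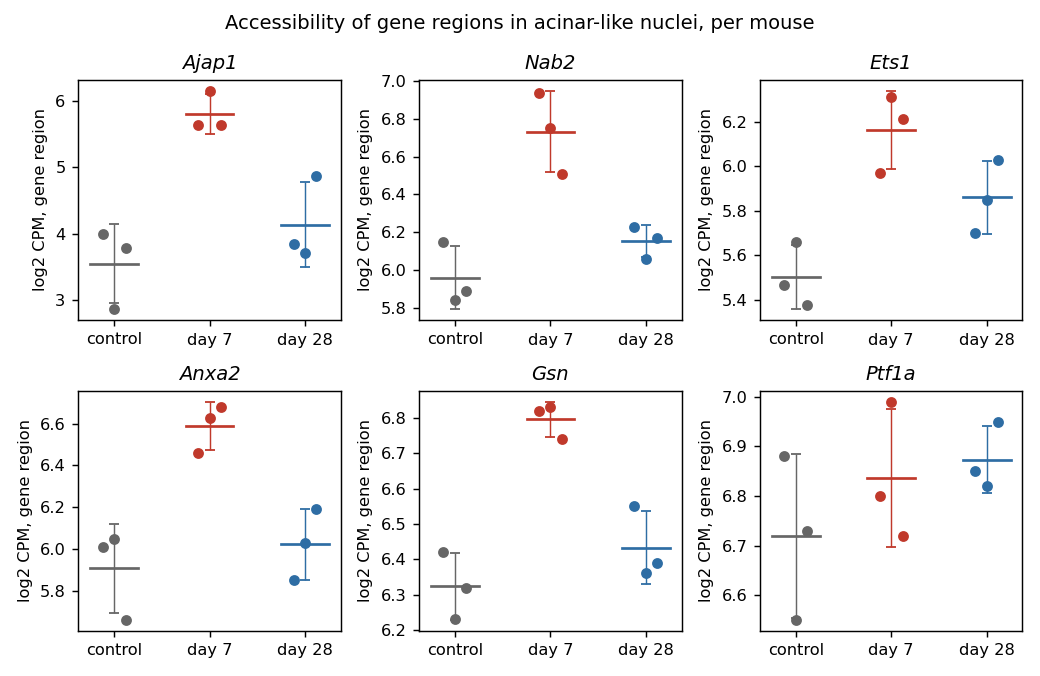
Accessibility (log2 CPM) of 6 gene regions in acinar-like nuclei; each point is 1 mouse, the bar is the group mean and the whiskers are the SD (n = 3 per group). Ajap1, Nab2, Ets1, Anxa2 and Gsn rose at day 7, with Ajap1 at 56.67 CPM against 12.36 in controls; Ptf1a did not pass the test (log2 change 0.12).

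Among single peaks of acinar-like nuclei, 75 rose and 12 fell at day 7 (n = 3 mice per group). Within Ets1, the peak at chromosome 9, 32705713-32706616, rose by a log2 change of 1.20 ± 0.15 SE (edgeR adjusted p = 0.00996), and the peak at chromosome 18, 67390361-67391113, in the beta-tubulin gene Tubb6, by 1.18 ± 0.15 (adjusted p = 0.0115). The peak in B3gnt3 (chromosome 8, 71701542-71702427) rose by 1.23 ± 0.20 (adjusted p = 0.0222), that in Kirrel3, which encodes an adhesion molecule (chromosome 9, 34485538-34486413), by 1.12 ± 0.17 (adjusted p = 0.0187), and a peak 370063 bp from Bcl11b (chromosome 12, 107539435-107540340) by 1.37 ± 0.25 (adjusted p = 0.0367). Of the falls named by the rule, 4 lay outside genes. They were 48629 bp from Ccdc172 (chromosome 19, 58601733-58602376; -1.06 ± 0.18, adjusted p = 0.025), 2458 bp from Cp, the ceruloplasmin gene (chromosome 3, 19953591-19954475; -1.05 ± 0.19, adjusted p = 0.0367), 63387 bp from Gas1 (chromosome 13, 60110138-60111018; -0.82 ± 0.13, adjusted p = 0.0222) and 65410 bp from Tle3 (chromosome 9, 61306015-61306916; -0.78 ± 0.13, adjusted p = 0.0222). Another peak that fell lay in Dym (chromosome 18, 75167901-75168831; -0.82 ± 0.16, adjusted p = 0.0485).

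Of the 75 raised peaks, 50 lay inside a gene, and their median log2 change was 1.05. At Ajap1 4 peaks within 13926 bp rose, by log2 changes of 1.75 to 2.42. Other raised peaks, picked after their values were seen and not tested as a group, lay at Cd44, a hyaluronan receptor (1.36), Krt7, a ductal keratin (1.25 and 1.24), Anxa2 (0.93 and 0.68), Anxa3 (1.00), S100a11 (1.25, at 13587 bp), Plaur, the urokinase receptor (1.03), and Fhl2 (1.51). At 823 bp from Dusp1, which encodes a phosphatase that switches off MAP kinases, a peak fell by 0.63 on the log2 scale (adjusted p = 0.032). The edgeR count of 87 became 0 without day 7 replicate 2 and with the gene-end covariate, 3 without control replicate 3, 25 without control replicate 1, 33 without control replicate 2, 39 without day 7 replicate 1, 1 without both 4-run libraries, 31 without control replicate 2 and day 28 replicate 2, 6 in the largest acinar-like cluster, 7 at 5000 to below 30000 counts, 226 with binarised counts and 653 with DESeq2. Of all peaks, 15.4% had the day 7 and control mice fully apart, against 10% by chance.

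Among the 15 gene lists fixed before the data were examined, genes of acinar-to-ductal metaplasia and injury, the programme in which acinar cells take on ductal features, rose as a list at day 7 in acinar-like nuclei at a preset correlation (limma's camera, adjusted p = 4.46e-07), but not with an estimated one (adjusted p = 0.497 with an estimated correlation). Of 28 measured, 22 stood higher (median log2 change 0.22). When adjusted over the list alone, 7 rose, among them Krt7 (0.78 ± 0.18), Cd44 (0.88 ± 0.18), Anxa2 (0.68 ± 0.11), Anxa3 (1.04 ± 0.19), Lgals3 (0.78 ± 0.18) and S100a11 (0.72 ± 0.14; log2 ± SE, n = 3 each). Over all genes 1 did, Anxa2. Sox9 (0.10 ± 0.10) and Krt19 (0.10 ± 0.14), ductal genes on the same list, did not pass. At the preset correlation the list's adjusted p without any 1 library was at most 0.000476, and it was 0.000668 without both 4-run libraries. At that correlation 3 lists passed for the real groups. As many passed in 8 of the 10 splits of the day 7 and control libraries, the real one included, with up to 7 in another. The number of lists passing therefore does not set the real groups apart.

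The extracellular matrix list also rose in acinar-like nuclei, with 15 of 18 genes higher, among them Fn1, which encodes fibronectin (0.39 ± 0.22), Sparc (0.42 ± 0.25) and Col4a2 (0.24 ± 0.12), and a median of 0.21. It passed camera at adjusted p = 0.00284, but not with an estimated correlation (adjusted p = 0.497 with an estimated correlation), and stood at 0.182 without control replicate 2. None of its genes was called over all genes or adjusted over the list alone. Cytosolic ribosomal protein genes, a control list, fell as a list: 31 of 38 were lower, with a median of -0.09 and none called either way. Their adjusted p was 0.00284 by camera, and adjusted p = 0.649 with an estimated correlation; they did not pass without day 7 replicate 2 or without control replicate 3 (highest adjusted p 0.881), nor without both 4-run libraries (0.903).

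MAPK feedback genes went both ways in acinar-like nuclei. When adjusted over the list alone Dusp4, a MAP kinase phosphatase, rose (0.66 ± 0.14), Il1rn, the interleukin 1 receptor antagonist, rose (0.57 ± 0.14), and Dusp1 fell (-0.37 ± 0.08; log2 ± SE, n = 3 each), and 0 changed over all genes. Camera gave adjusted p = 0.764 for the list, whose median was -0.01 and mean 0.04, and limma's fry test, a rotation test of change in either direction, gave 1.43e-05 unadjusted. Fry values of the other lists, the control lists included, are not given here, so how unusual this value is cannot be told. Adjusted over the list alone Ptpn14 of the YAP and TEAD targets (0.41 ± 0.10; list adjusted p = 0.18) and Lif of the NF-kB and cytokine list (0.51 ± 0.13; list adjusted p = 0.211) also rose, and neither over all genes.

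The acinar identity lists did not pass at day 7. Acinar-like nuclei were named by acinar markers, so a nucleus that lost their accessibility could fall outside the class. These lists therefore cannot show whether acinar identity was kept. Of the digestive enzymes 12 of 23 were higher (median 0.02, mean 0.00, direction of the test down; adjusted p = 0.463), with Cpa1 at -0.09 ± 0.10 and Cel at 0.13 ± 0.14. Of the acinar transcription factors 9 of 13 were higher (adjusted p = 0.294), with Ptf1a at 0.12 ± 0.09 and Nr5a2 at -0.04 ± 0.08. Nor did the Reg family (7 of 7 higher, adjusted p = 0.18), AP-1 and immediate early genes (6 of 21 higher, 0.294), with Fos at -0.05 ± 0.08 and Jun at -0.08 ± 0.07, or the unfolded protein response (14 of 25 higher, 0.463), with Hspa5 at 0.03 ± 0.09. Interferon response (9 of 14 higher, 0.103), proliferation (14 of 34 higher, 0.999), Notch, Wnt and Hedgehog genes (19 of 27 higher, 0.0859) and housekeeping genes (4 of 15 higher, 0.418) did not pass. None of these lists had a member called adjusted over the list alone or over all genes. The 15 marker lists of cell types with at least 3 measured genes did not pass in acinar-like nuclei (lowest adjusted p = 0.144, for macrophage and tuft markers). Among single markers C1qa of macrophages (0.42 ± 0.14), Bcl11b of T or NK cells (0.44 ± 0.13) and Krt7 of duct stood higher adjusted over their list alone.

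Summed over all nuclei, 43 peaks rose and 6 fell at day 7 against controls, and 48 of these 49 were among the 87 of the acinar-like nuclei. These sums contain the acinar-like nuclei, which in control replicate 1, for example, held 36464148 of 40757452 counts. The overlap was therefore largely fixed in advance, and these sums are no separate test of the acinar-like results. By the naming rule the peak in Cblif (chromosome 19, 11755226-11756163) rose by a log2 change of 1.12 ± 0.19 SE (edgeR adjusted p = 0.041, n = 3 each), the Ets1 peak by 1.14 ± 0.14 (adjusted p = 0.0155), the Bcl11b peak by 1.38 ± 0.25, the Kirrel3 peak by 1.08 ± 0.17 and the B3gnt3 peak by 0.98 ± 0.18. Among the falls were peaks 124677 bp from Trim29 (chromosome 9, 43460802-43461690; -0.69 ± 0.12, adjusted p = 0.0482) and 823 bp from Dusp1 (chromosome 17, 26503908-26504768; -0.60 ± 0.11, adjusted p = 0.0482), and those near Ccdc172 (-1.04 ± 0.18), Gas1 (-0.76 ± 0.12) and Tle3 (-0.73 ± 0.12). The injury list rose here too (22 of 28 higher, median 0.19, camera adjusted p = 3.04e-06, with adjusted p = 0.625 with an estimated correlation). Adjusted over the list alone 6 of its genes rose, among them Krt7, Cd44, Anxa2, Anxa3 and S100a11, and 0 over all genes. Ribosomal protein genes fell as a list (35 of 38 lower, median -0.08, adjusted p = 0.000769, with adjusted p = 0.625 with an estimated correlation; 0.462 without day 7 replicate 2). The extracellular matrix list stood at 0.0776, and no marker list passed (lowest adjusted p = 0.109, for ductal, macrophage and tuft markers). Adjusted over their list alone Dusp4, Il1rn, Ptpn14, Lif, Bcl11b and Flt1, an endothelial receptor gene, rose and Dusp1 fell, with 0 over all genes.

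No gene passed over all nuclei at day 7: edgeR called 0, with 1074 at an unadjusted p under 0.05, and DESeq2 called 79. The edgeR count was 2 without day 28 replicate 2, 1 without day 28 replicate 3, 2 with binarised counts and 2 without control replicate 2 and day 28 replicate 2. The 49 peaks became 0 without control replicate 3, without day 7 replicate 2 or with the gene-end covariate, 1 without control replicate 1 or without both 4-run libraries, 3 without control replicate 2, 4 without day 7 replicate 1, 79 without day 7 replicate 3, 30 without day 28 replicate 2, 31 with relative log expression scaling, 29 without the 5% deepest nuclei, 9 without control replicate 2 and day 28 replicate 2, 129 with binarised counts and 464 with DESeq2.

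At day 28 no single gene or peak passed against controls, and the injury and Reg gene lists rose only at a preset correlation (adjusted p = 0.593 for each with an estimated correlation). In acinar-like nuclei 24 of 28 injury genes were higher (median log2 change 0.08), with Anxa3 at 0.66 ± 0.19, Cd44 at 0.48 ± 0.19 and Lgals3 at 0.47 ± 0.19 (log2 ± SE, n = 3 each). Camera gave adjusted p = 1.31e-05 for the injury list at the preset correlation. All 7 Reg genes, which encode secreted lectins, were higher (median 0.19), among them Reg1 (0.36 ± 0.25) and Reg3b (0.33 ± 0.24), at adjusted p = 0.000755. Reg3a and Reg3d had identical values (0.16 ± 0.11), yet each counted as 1 of the 7 members in the test, so the members were not independent. All 10 ductal markers were higher too (median 0.08), at adjusted p = 0.0116 and adjusted p = 0.437 with an estimated correlation; Krt19, Krt7, Sox9, Muc1, Spp1 and Onecut2 among them are on the injury list as well. In none of the 3 lists was a member called over all genes or adjusted over the list alone.

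With edgeR the count at day 28 was 0 for genes (191 at an unadjusted p under 0.05) and 0 for peaks (1086) in acinar-like nuclei, and 0 for genes (172) and 0 for peaks (994) over all nuclei, and DESeq2 also called 0 in each. Genes with all day 28 and control mice apart made up 4.9% in acinar-like nuclei, against 10% by chance. The other gene lists did not pass in acinar-like nuclei (adjusted p = 0.0667 for extracellular matrix, proliferation, and YAP and TEAD targets, 0.188 for AP-1 genes and 0.385 or more for the rest), and the tuft markers stood at 0.0936. Digestive enzymes (median -0.01, mean 0.02, direction up, adjusted p = 0.767) and Notch, Wnt and Hedgehog genes (-0.01, 0.02, up, 0.459) differed in sign between median and mean. The injury list was lost without control replicate 2 (adjusted p = 0.176), the Reg list without control replicate 2 or day 28 replicate 1 (highest 0.348), and the ductal markers without control replicate 2, day 28 replicate 1 or day 28 replicate 2 (highest 0.457). Over all nuclei the same 3 lists rose: 25 of 28 injury genes were higher (median 0.08, adjusted p = 0.000572), 7 of 7 Reg genes (0.20, adjusted p = 0.000572) and 10 of 10 ductal markers (0.07, adjusted p = 0.00428). These became adjusted p = 0.681, 0.681 and 0.528 with an estimated correlation. Each was lost without control replicate 2, the injury list also without day 28 replicate 3 and the other 2 lists without day 28 replicate 1 (highest 0.37, 0.37 and 0.486), and the injury list stood at 0.103 without both 4-run libraries.

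The 75 peaks raised at day 7 in acinar-like nuclei had a median log2 change of 1.05 at day 7 and 0.33 at day 28. At day 28, 72 of them were above 0 and 32 had an unadjusted p under 0.05, although 0 were called. Of the 12 lowered peaks, 10 were lower at day 28. For the 16 raised genes the medians were 0.87 and 0.26, with 15 above 0, and Cblif stood at 0.72, Ajap1 at 0.61, Ets1 at 0.36 and Fam3b at -0.06 at day 28. Both comparisons used the same 3 controls, which alone gives a positive relation. Across 15592 genes, which are not independent replicates, the covariance of the log2 changes was 0.00996 (r = 0.50), and 100 simulations of unchanged groups against those controls gave 0.0098 (highest 0.0104; r = 0.50). Across peaks it was 0.0184 (r = 0.48), against a simulated 0.0194 over 20 draws (r = 0.50), and -0.00652, -0.0034 and 0.00254 against held-out controls. With day 28 set against 1 held-out control at a time, the gene covariance was -0.00874, 0.0018 and -0.000158 for control replicates 1, 2 and 3. Independent lists would share 0 genes, since day 28 had 0 calls, and 3 controls cannot be divided into parts of at least 2.

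**Figure D3:**
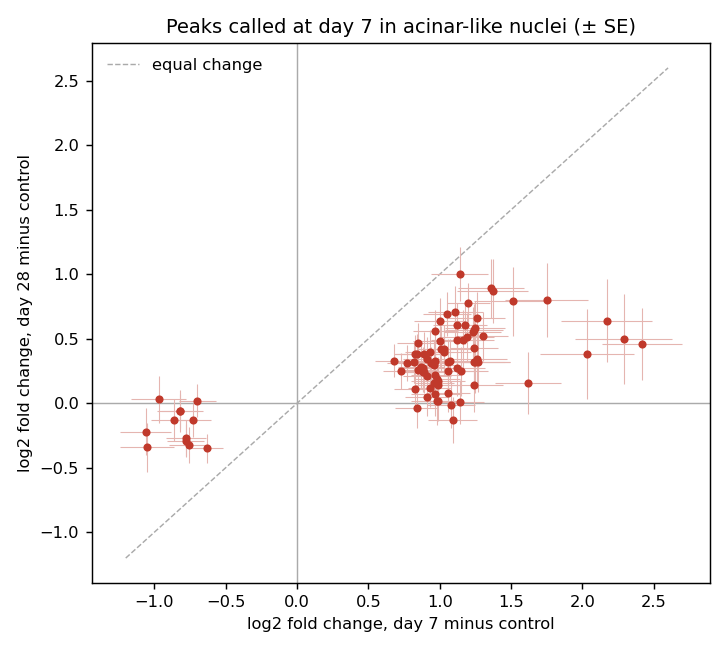
Log2 fold change against controls at day 7 (horizontal) and day 28 (vertical) of the 87 peaks called at day 7 in acinar-like nuclei; each point is 1 peak, the whiskers are standard errors and the dashed line marks equal change. The 75 raised peaks had medians of 1.05 at day 7 and 0.33 at day 28; both axes use the same 3 controls.

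Between day 7 and day 28, 4 peaks fell in acinar-like nuclei. In Ajap1 (chromosome 4, 153425713-153426606) accessibility went from 16.96 ± 2.55 CPM at day 7 to 4.454 ± 2.46 at day 28 (mean ± SD, n = 3 each; log2 change -1.95 ± 0.27 SE), beside 3.199 ± 0.771 in controls. In Ephb1, an ephrin receptor gene (chromosome 9, 102189117-102190033), it went from 11.91 ± 0.632 to 5.13 ± 1.35 CPM (-1.22 ± 0.17), with controls at 5.608 ± 0.689. The others lay 1622 bp from Ggnbp1 (chromosome 17, 27038000-27038902; -1.12 ± 0.17) and 35745 bp from Hs1bp3 (chromosome 12, 8379569-8380463; -1.03 ± 0.15). Each had edgeR adjusted p = 0.0492, with every day 28 mouse below every day 7 mouse. The peaks of Ajap1, Ephb1 and Ggnbp1 were picked after their values were seen, and that of Hs1bp3 passed the naming rule.

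Injury genes fell as a list from day 7 to day 28 in acinar-like nuclei, 22 of 28 being lower (median -0.12, camera adjusted p = 0.0124, with adjusted p = 0.801 with an estimated correlation). Anxa2 fell adjusted over the list alone (-0.57 ± 0.11), and 0 genes over all genes. Ribosomal protein genes rose as a list (31 of 38 higher, median 0.07, adjusted p = 0.000969, with adjusted p = 0.801 with an estimated correlation), with none called either way. C1qa (-0.48 ± 0.14) was lower adjusted over the macrophage list alone, and that list did not pass (adjusted p = 0.196), nor did interferon genes (0.0793), the extracellular matrix list (0.156), MAPK feedback genes (median 0.03, mean -0.02, direction down, 0.906) or the other gene lists (0.266 or more). The injury list was lost without day 7 replicate 2 or day 28 replicate 1 and the ribosomal list without day 7 replicate 2 (highest 0.737 for each), and both stood at 0.327 without both 4-run libraries. Over all nuclei 21 of 28 injury genes were lower (median -0.11, adjusted p = 0.0112) and 31 of 38 ribosomal genes higher (0.07, adjusted p = 0.00103), both with adjusted p = 0.865 with an estimated correlation; the injury list was lost without day 7 replicate 2 (0.669) or day 28 replicate 1, the ribosomal list without day 7 replicate 2 (0.776).

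The 4 peaks from edgeR (4300 at an unadjusted p under 0.05) became 0 without control replicate 3, without any 1 of the 3 day 7 libraries, without day 28 replicate 1 or day 28 replicate 2, with relative log expression scaling, binarised counts, the higher cluster resolution or the gene-end covariate, without the 5% deepest nuclei, in the largest acinar-like cluster, at 5000 to below 30000 counts or without control replicate 2 and day 28 replicate 2. They were also 0 with the replicate number as a block. They were 1 without both 4-run libraries, 2 after thinning, 9 without control replicate 2, 7 without day 28 replicate 3 and 225 with DESeq2. No gene passed in acinar-like nuclei (0 with edgeR, 814 at an unadjusted p under 0.05, 25 with DESeq2 and 3 without control replicate 2) or over all nuclei (0, 713 and 18). Over all nuclei 0 peaks passed with edgeR (4087 at an unadjusted p under 0.05, 167 with DESeq2), with 6 without control replicate 2, 4 without day 28 replicate 3, 1 without both 4-run libraries and 1 after thinning. The smallest edgeR adjusted p over all nuclei was 0.467 for genes and 0.12 for peaks, the latter at Ajap1 (-1.94 ± 0.27) and at Ephb1 (-1.11 ± 0.17).

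In the other classes with at least 30 nuclei in every library, 1 gene passed across the 3 comparisons. Esrp1, a splicing regulator of epithelial cells, rose at day 7 in endothelial-like nuclei (log2 change 3.14 ± 0.53 SE, edgeR adjusted p = 0.00606, n = 3 each), and was picked after its values were seen. In acinar-like nuclei Esrp1 stood at 179.0 ± 10.4 CPM in controls, with a day 7 log2 change of -0.01 ± 0.07. In ductal-like nuclei edgeR called 0 of 14843 genes, with 821, 803 and 753 at an unadjusted p under 0.05 for day 7, day 28 and day 28 against day 7. In fibroblast-like nuclei it called 0 of 14730, with 608, 607 and 632, and in macrophage-like nuclei 0 of 12895, with 443, 573 and 774. Chance alone gives a share of about 0.05 of the genes tested, and these counts lie near or below it. DESeq2 was not run on these classes. Of the 16 genes raised in acinar-like nuclei, 8 of 15 measured were higher at day 7 in ductal-like nuclei (median log2 change 0.06), 10 of 14 in fibroblast-like nuclei (0.115), 8 of 10 in macrophage-like nuclei (0.19) and 6 of 10 in endothelial-like nuclei (0.06), with 0 called. Of these genes, 4 in ductal-like, 1 in fibroblast-like, 1 in macrophage-like and 0 in endothelial-like nuclei had an unadjusted edgeR p under 0.05, in either direction. Simulated 2-fold changes at day 7 were called in 97% of genes in acinar-like and 63% in ductal-like nuclei. They were called in 51.5% in fibroblast-like, 30.9% in macrophage-like and 8.4% in endothelial-like nuclei. Esrp1 was not called without control replicate 1 (adjusted p = 0.0625), control replicate 3 (0.0995), day 7 replicate 2 (0.952) or both 4-run libraries. The count of 1 was 5 without control replicate 2, 2 without day 7 replicate 1, 5 without day 7 replicate 3 and 2 without day 28 replicate 3, and leaving out day 28 replicate 1 gave 41 calls, 39 of them lower at day 28 than at day 7 in endothelial-like nuclei.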

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

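No test in this part was chosen only after its result was seen. Each result here was singled out because the cerulein groups differed from each other in the comparison of day 28 with day 7 in acinar-like nuclei. All controls were sacrificed at day 28. A changed effect of cerulein therefore cannot be told from another difference between the time points. The peaks were those in Ajap1 (log2 change -1.95), in Ephb1 (-1.22), near Ggnbp1 (-1.12) and near Hs1bp3 (-1.03). At Ajap1 the day 7 mice stood at 16.96 CPM, the day 28 mice at 4.454 and the controls at 3.199, and at Ephb1 at 11.91, 5.13 and 5.608. The lists were those of acinar-to-ductal metaplasia and injury (lower, adjusted p = 0.0124, and adjusted p = 0.801 with an estimated correlation) and of cytosolic ribosomal proteins (higher, adjusted p = 0.000969, and adjusted p = 0.801 with an estimated correlation). With 3 mice per time point in 1 cage each, a cage difference cannot be told from a time difference.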

How the results depend on the processing

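The added alternatives named in the methods were chosen after the data were seen, some of them after the calls were. Of 373 values of 21 results under alternatives, 257 stayed on their side or within 1.5 times and 116 moved; the cause was not tested. The covariance changed sign against held-out controls 1 and 3. Day 28 against control gave 0 genes and 0 peaks under every alternative, and class shares 0. Of 553 comparisons of 25 named genes and peaks, 290 were the same, 263 lost the call and 0 reversed; 0 of 25 were called without day 7 replicate 2, with the gene-end covariate or without both 4-run libraries. For the 75 raised acinar-like peaks alone, the fold was compared in 9 alternatives. All 75 were higher in each, with medians of 0.93 to 1.09 against 1.05. These peaks and the named items were chosen for their change in the same libraries, so their direction was largely fixed in advance. Of the 75 peaks, between 0 (gene-end covariate) and 65 (thinned to equal totals) were still called.

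With 1 library left out, counts ranged as follows for day 7, day 28 and day 28 against day 7: acinar-like genes 0 to 18, 0 to 0 and 0 to 3; acinar-like peaks 0 to 116, 0 to 0 and 0 to 9. Over all nuclei they were 0 to 2, 0 to 0 and 0 to 0 for genes and 0 to 79, 0 to 0 and 0 to 6 for peaks. Lists ranged from 2 to 5, 1 to 5 and 1 to 5 in acinar-like nuclei and from 2 to 5, 0 to 12 and 1 to 6 over all nuclei, and calls in other classes from 0 to 41.

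For day 7 genes in acinar-like nuclei (16) the count was 27 with the replicate block, 0 without both 4-run libraries, 8 without the 5% deepest nuclei, 8 in the largest cluster, 0 at 5000 to below 30000 counts, 6 at gene ends, 8 without control replicate 2 and day 28 replicate 2, 0 with the covariate and 123 with DESeq2. For day 7 peaks there (87) it was 1 without both 4-run libraries, 226 binarised, 6 in the largest cluster, 7 at 5000 to below 30000 counts, 31 without control replicate 2 and day 28 replicate 2, 0 with the covariate and 653 with DESeq2. For day 28 against day 7 it was, for genes (0), 2 with the block and 25 with DESeq2, and for peaks (4), 0 with relative log expression, the block, no 5% deepest nuclei, binarised counts, the higher resolution, the largest cluster, 5000 to below 30000 counts, the covariate or without control replicate 2 and day 28 replicate 2, 1 without both 4-run libraries, 2 thinned and 225 with DESeq2.

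Over all nuclei, day 7 genes (0) were 2 binarised, 2 without control replicate 2 and day 28 replicate 2 and 79 with DESeq2. Day 7 peaks (49) were 31 with relative log expression, 1 without both 4-run libraries, 29 without the 5% deepest nuclei, 129 binarised, 9 without control replicate 2 and day 28 replicate 2, 0 with the covariate and 464 with DESeq2. Day 28 against day 7 gave 18 genes with DESeq2 (0), and peaks (0) 1 without both 4-run libraries, 1 thinned and 167 with DESeq2. With an estimated correlation 0 lists passed in any comparison; day 7 acinar-like lists (3) were 5 at gene ends and day 28 all-nuclei lists (3) 6 with the block. Other classes (1) gave 6 with the block and 0 without both 4-run libraries. The covariance (0.00996) was -0.00874, 0.0018 and -0.000158 against held-out controls 1, 2 and 3.

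With the block 15 of the 16 genes and 72 of the 87 peaks were still called. Only 4 of 9 libraries correlated best with their own replicate number. Apart from the counts given for the block above, it moved none by over 1.5 times. Motif accessibility and the promoter-only alternative were not run. At this depth and with 3 libraries against 3, 25% of 1.5-fold changes of peaks were called in simulated acinar-like data, and which of the 2 limits them was not tested.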

Other observations

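The tests of the 4-run libraries by recalling peaks, of the share of counts at gene ends, of shared controls and of a mislabelled pair were chosen, or their rules changed, only after the result was seen. The other tests were written before a first run in single precision and were rerun on the double-precision clusters. Control replicate 3, day 7 replicate 2 and day 28 replicate 3 had more counts than the other libraries of their group in acinar-like nuclei at Cdk8, a kinase of the Mediator complex (log2 CPM 8.74, 8.99 and 8.65, against 7.29 to 8.00 in the others), and at Cmss1 (8.27, 8.56 and 8.20, against 7.06 to 7.60). Filip1l, within the Cmss1 region, stood at 8.17, 8.50 and 8.11. These genes were picked after their values were seen, and no explanation was tested.

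Of the peaks raised at day 7 in acinar-like nuclei, chromatin of any single other class, as seen in control nuclei, was excluded as the whole cause. Of the 75 raised peaks, 53 were more accessible in ductal-like than in acinar-like control nuclei, and 32 to 43 in each of the other classes. Mixed in at the share that accounts best for the raised peaks (17%), ductal-like chromatin accounts for a median log2 change of 0.29 of their 1.05. At that share it predicts a median of 1.60 at its 500 most specific peaks. There 0.23 was seen, and 0.15 to 0.22 at the specific peaks of the other classes. The SE of 0.016 is over the 500 peaks of a class and does not measure the spread between mice. A part of the rise coming from another class was not excluded. Several classes together, or a class itself changed at day 7, were not tested. The library pooled from 4 runs cannot be told from the effect. Among the 100 peaks most raised in that day 7 library, the 6-run day 7 libraries minus a held-out control had medians of 0.44, 0.42 and -0.19. The first 2 were above the upper limit of random sets (0.04) and the last below their lower limit (-0.04). These limits are percentiles of the random sets, not their extremes. The 4-run day 28 library had 0.50, 0.40 and 0.17 at the same peaks. Also, 1 raised peak was called without the 4-run libraries, with a median of 1.00 against 1.05. With the share of counts at gene ends as a covariate, which was 48.23% in day 7 replicate 2 and 50.08 to 51.58% in the others, the median was 1.01 and 0 peaks were called, so that test cannot tell either.

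Control replicate 2 and day 28 replicate 2 stood apart on the first principal component of acinar-like nuclei (37.2% of variance; 27.0 and 16.0 against -15.5 to 0 in the others). The same genes deviated in the other classes of these libraries, with slopes of 0.64 to 0.88 on the acinar-like deviation, which fits a library-wide difference. The correlations across genes were 0.19 to 0.51, and other ways in which these classes could share the deviation were not tested. An exchange of their labels was excluded as the cause: both lie on the same side, the lower at 16.0, above every other library of both groups (-6.9 to 0), so exchanging them leaves both apart. No biological explanation was tested.

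Peaks raised at day 7 were also higher at day 28, a pattern that shared controls alone can give, to an extent that was not settled here. The 75 raised peaks of smallest p were chosen without 1 control, and day 28 was set against that control. The medians were 0.09, 0.17 and 0.30, each above the upper limit of random sets (0.06, 0.09 and 0.09). For genes the medians were 0.01, 0.19 and 0.14 (upper limits 0.06, 0.08 and 0.07), the first within the limits. These limits are percentiles of the random sets, not their extremes. This version of the test replaced a first one after its result was seen. The first used only the peaks called without the held-out control and gave 0.12, 0.17 and 0.24. The upper limits of random sets were 0.12, 0.13 and 0.31, so only control replicate 2 was clearly above. In the replacing version a rise at the peaks was left against each held-out control, with 0.09 as the lowest value. The versions differ, and the change was made after a result was seen, so shared controls stay open as the cause. The covariance across all peaks was 0.0184, below that simulated without change (0.0194). Against held-out controls it was -0.00652, -0.0034 and 0.00254. It cannot settle the question, because the raised peaks are a small part of all peaks.

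With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The number of splits with as many calls as the real one, itself included, and the highest count of another split were, for day 7, day 28 and day 28 against day 7: acinar-like peaks 1 and 0, 10 and 0, 1 and 2; acinar-like genes 1 and 0, 10 and 1155, 10 and 0; peaks over all nuclei 1 and 0, 10 and 0, 10 and 1; genes over all nuclei 10 and 0, 10 and 937, 10 and 0. For lists in acinar-like nuclei they were 8 and 7, 8 and 6, 8 and 8, and over all nuclei 10 and 8, 9 and 8, 9 and 11. Most splits thus passed as many lists at the preset correlation, so their number does not set the real groups apart. For other classes the values were 3 and 2, 10 and 53, 10 and 18. The split with 1155 genes set control replicates 1 and 3 and day 28 replicate 1 against control replicate 2 and day 28 replicates 2 and 3, which points to a structure of the samples.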
